A study of Homo sapiens with 10 samples.

How the data were processed

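Gene expression was measured in 8 bulk and 2 single-cell human libraries. The bulk files hold raw counts per gene symbol, which the authors made with HTSeq from Lexogen QuantSeq forward 3′ libraries; the labels also name UMI-tools, cutadapt, TopHat, TopHat2 2.0 and DESeq2, and both hg19 and GRCh38, so no coordinates are given here. Whether these counts are of unique molecules is not given in the sources used here. The single-cell files hold raw molecule counts per gene and barcode, deposited without normalization, from 10x Genomics 3′ libraries; the labels name Cell Ranger, Seurat 4.0.4 and GRCh38. The labels speak of nuclei in places and of trypsinised, strained cells in others, and the barcodes carried mitochondrial molecules (medians of 5.64% and 8.78% in kept cells). The poorest deposited barcode held 390 genes at low and 220 at high passage.

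Bulk samples were grouped by their labels as day 25, day 50, day 100 and primary, with 2 libraries each, and no library was moved. Of 31631 genes listed, 17295 passed filterByExpr of edgeR 4.0.16 in R 4.3.3. Totals of 33480954 to 42567706 counts were scaled with TMM factors, and all 8 libraries entered 1 quasi-likelihood fit with a mean per group. Contrasts of days, of each day with primary, and of the mean of the 3 days with primary were tested two-sided with Benjamini-Hochberg adjustment at 0.05 over the genes tested. The 26 gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 and again with an estimated one, and with fry, each adjusted over the lists of a contrast. Camera compares a list with all other genes; fry asks whether its members move one way on balance. No list in the 4 contrasts tested was called with an estimated correlation. Levels are CPM; errors are SD for CPM and SE for log2 folds. Pairs of libraries were compared by the median chi-square of each gene's counts over its chance value. Spearman correlations with primary libraries were taken across tested genes.

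Genes were named by a rule: per contrast the 8 with the largest fold in each direction among those past the test and at 20 CPM or more in every library of the higher side, up to 4 members per list with the smallest p, and a fixed set that included SOX10, S100B, PMP22, NGFR, GFAP, ERBB3, MBP and POU5F1. Some genes that the rule names are not reported here. In single cells it took the 10 largest ratios in each direction and up to 4 members per list with the most counts. The lists, the naming rule, the tests, the filters and the alternatives were fixed before the data were examined, except where stated. DCT, COL1A1, HOXC11, HOXB2, HOXB3, HOXB9, MSX1, LOC654433, XLOC_006252 and the genes that open the other observations fell outside the rule and were chosen after their values were seen.

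Barcodes with at least 500 genes and at most 20% mitochondrial counts were kept. Doublets were called with a scrublet-style score written in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and scikit-learn 1.9.0, with thresholds of 0.22 and 0.386 set from simulated doublets; 2588 (14.4%) and 1436 (6.7%) barcodes were removed, so the removal was uneven. Counts were scaled to 10000 per cell, logged, and reduced to 30 components of 2000 variable genes, without integration. Leiden clusters (leidenalg 0.10.2, igraph 0.11.9) were drawn on 15 neighbours at resolution 0.5 and named from fixed markers when at least 3 were 2-fold higher than in other cells. The fold was taken with 20 CPM added to both sides, and the class needed more such markers than any other. No name was given where another class had more markers among the 10 top genes. A cluster whose median molecules were under 1/3 of its main library's median also needed a marker among those 10. Ratios compare CPM of counts summed over kept cells, with exact conditional binomial (Clopper-Pearson) intervals at 95% and exact Poisson intervals for levels; shares of cells have Clopper-Pearson intervals. A gene counted as 2-fold different at a ratio of at least 2, a level of at least 50 CPM in 1 library and an interval beyond 1. List medians used members at 5 CPM or more and were placed among 10000 random lists matched on expression in 20 bins. With 1 library per passage no test between passages was made.

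The pipeline was tested on simulated data. With the spread estimated from all 8 libraries, a planted 2-fold change between groups of 2 was recovered in 10.4% of genes, a 4-fold change in 73.1% and a 16-fold change in 100%, with 7 of 16737 unchanged genes called. With the lower spread of day 25 and day 100 alone these were 70.1%, 100% and 100%, with 12 of 16741 called. Both bulk simulations gave every group the same spread and were tested in the fit of all 8 libraries. In the data the spread differed between groups, so these rates need not carry over. They also do not cover the fit of day 25 and day 100 alone. In single cells, planted 4-fold ratios were called in 50 of 50 genes and planted ratios of 2 and 0.5 in 32 and 28 of 50. Of 2577 unchanged genes 0 were called, and intervals held the planted ratio in 90.0% to 96.0% of genes. These counts were drawn with counting error alone, which the intervals assume, so unchanged genes could hardly reach a ratio of 2. The 0 calls therefore say nothing on spread between cultures or libraries.

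Alternatives covered scaling (RLE size factors, library totals), the low-count filter (none, or 10 CPM in 2 libraries), DESeq2 1.42.0, a robust fit, a replicate block, a test against a fold of 2 (glmTreat), fits of only the groups compared, each library left out in turn, and for single cells the barcode filter, doublets, thinning to 2000 molecules, scaling, resolution and the CPM minimum. Scaling moved the median log2 fold of all genes by less than 0.1. An H9-derived mean without the day 50 libraries, and clustering of each library on its own, were added after seeing the data. Alignment and raw reads were not analysed here.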

Results

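Bulk RNA was counted in 8 libraries by sequencing from transcript 3′ ends. Schwann cells derived from H9, an established human embryonic stem cell line, gave 2 libraries each at day 25, day 50 and day 100 of differentiation, and primary human Schwann cells gave another 2. Counts within genes came to 40320856 and 42567706 at day 25, 38484621 and 33480954 at day 50, 41869589 and 40885511 at day 100, and 38261023 and 34474728 in the primary cells, in replicate order. Single-cell RNA was counted in 2 further libraries of H9-derived Schwann cells, 1 at low passage with 156779758 molecules in 22745 barcodes and 1 at high passage with 182965790 in 24325. Each of these pooled cells from 2 separate differentiations, so neither carries a measure of spread between cultures. The labels do not say whether bulk replicates came from separate cultures or donors, so every p-value measures only the spread between these libraries. Intervals and floors cover counting error only.

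The day 50 libraries differed from each other far more than most replicates did. Among genes at 10 CPM (counts scaled by library total) or more, 19.5% of 10513 were at least 2-fold apart between them, against 0% of 10013 between the day 25 libraries, 2.88% of 9757 at day 100 and 10% of 10294 in the primary cells. The library labelled day 50 replicate 1 stood beside the day 25 libraries: 0% of 10011 genes were 2-fold apart from day 25 replicate 1, though their counts differed by 1.76 times the chance spread and so were not identical. VCAN, a matrix proteoglycan gene, read 1160 CPM in that library, 1030 and 1120 at day 25, and 72.5 in day 50 replicate 2. DCT, a pigment synthesis gene chosen after its values were seen, read 4090, then 3990 and 5110, and then 34.6 CPM in the same order. Day 50 replicate 2 lay nearest to day 100 replicate 1, with 2.84% of 9841 genes 2-fold apart. The primary libraries also differed in Schwann and matrix markers: SOX10 read 261 and 53.4 CPM, NGFR 1400 and 325, and COL1A1, also chosen after its values were seen, 2930 and 10000, in replicate order.

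**Figure D1:**
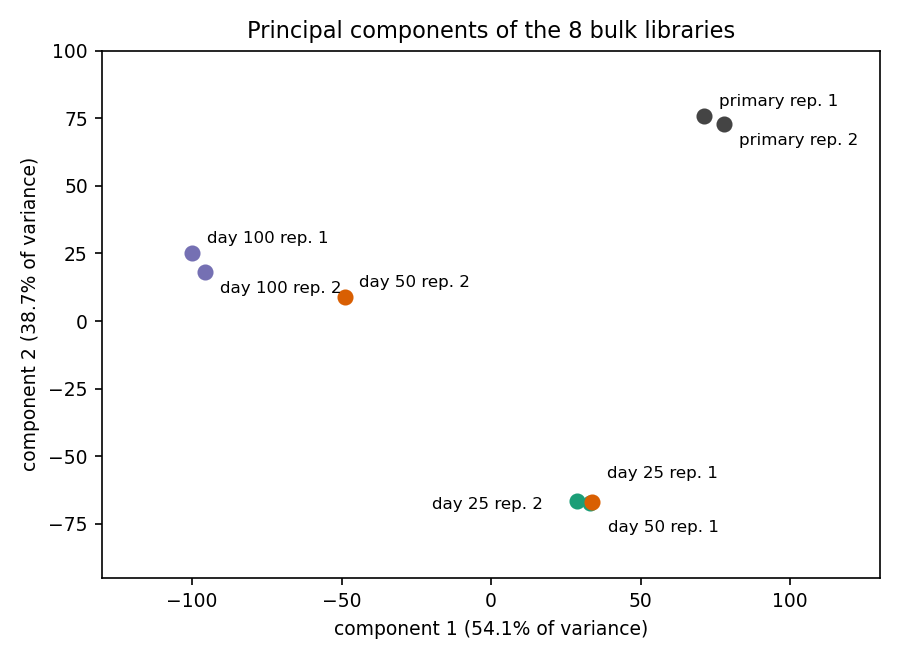
Each point is 1 of the 8 bulk libraries on the first principal components of log2 CPM, component 1 (54.1% of variance) across and component 2 (38.7%) up, coloured by group. The point of day 50 replicate 1 covers that of day 25 replicate 1, and day 50 replicate 2 lies towards day 100.

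The H9-derived cells at all 3 days were set against primary Schwann cells to ask how closely the derived cells resemble them. Pigment cell genes were higher in the derived cells. PMEL, which builds the fibrils of melanosomes, averaged 9770 CPM ± 3150 (SD, n = 6) in the H9-derived libraries and 4.19 ± 2.5 (SD, n = 2) in the primary ones, a log2 fold of 11.16 ± 0.69 (SE, adjusted p = 0.00037). TYR, the rate-limiting enzyme of melanin synthesis, stood at 1050 CPM ± 204 against 0.434 ± 0.467, and TRPM1, a melanocyte channel gene, at 118 ± 21.2 against 0.148 ± 0.0615. All 11 measured melanocyte genes were higher, and all 11 when adjusted over the list alone, with a median log2 fold of 9.06. MITF, the master regulator of the lineage, rose by 6.48 ± 0.33 and the melanosome receptor gene GPR143 by 7.48 ± 0.51. The list was called by camera (adjusted p = 2.51e-12; adjusted p = 0.201 with an estimated correlation) and by fry (adjusted p = 7.98e-05). Without day 50 replicate 1 all 11 were still higher.

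Schwann cell genes went both ways. NGFR, the low-affinity neurotrophin receptor of immature and repair Schwann cells, averaged 51.7 CPM ± 24.2 (SD, n = 6) in the H9-derived libraries and 865 ± 763 (SD, n = 2) in the primary ones, a log2 fold of -4.15 ± 0.53 (SE, adjusted p = 0.0035), while the adhesion gene L1CAM was higher in the H9-derived cells (3.12 ± 0.38). PMP22, a compact myelin gene, was also lower (-2.21 ± 0.54), and GFAP, an intermediate filament gene of nonmyelinating glia, was lower by -4.21 ± 0.81 but stayed under 1 CPM in every library. Several lineage genes did not pass the test: SOX10, the glial master regulator, had a log2 fold of 1.44 ± 0.56 (adjusted p = 0.11), ERBB3, the neuregulin receptor, 2.23 ± 0.68 (0.057), S100B -1.12 ± 0.55 (0.19) and MBP 0.68 ± 0.78 (0.57). Of 19 Schwann lineage genes, 2 were higher, 6 lower and 11 did not pass, or 3 and 6 adjusted over the list alone. The lower ones included SEMA3B (-4.66 ± 0.42) and the small heat-shock gene CRYAB (-4.81 ± 0.5). The myelin list had 2 higher, GLDN and MPDZ, and 3 lower among 19, the same adjusted over the list alone. Among 16 immature and precursor Schwann genes, 4 were higher, including the neural crest factor PAX3 (4.82 ± 0.67), and 4 lower, including the growth-cone gene GAP43 (-1.12 ± 0.17), or 5 and 4 adjusted over the list alone. GAP43 was below the primary level only at day 100, where it read 0.636 and 0.819 CPM. It read 34.8 to 43.2 CPM at day 25 and day 50, against 23.8 and 21.4 in the primary cells. None of these Schwann cell lists was called by camera or fry. The primary libraries themselves differed in these markers, as given above.

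HOX genes, which mark position along the body axis, were lower in the mean of the H9-derived cells, although day 50 replicate 2 departed from the other libraries. It read HOXB3 at 15.5 and HOXB2 at 15.4 CPM, both chosen after their values were seen, against means of 27.7 and 25.1 in the primary cells, and HOXB9, given below, above the primary level. Of 31 measured, 27 were lower and 30 were when adjusted over the list alone, with a median log2 fold of -7.45, or -7.28 with the 5 genes that had 0 counts in all 6 libraries set at their bound. HOXA10 (-9.34 ± 0.71) and HOXC8 (-9.49 ± 0.69), genes of posterior segments, were lower, and HOXC11, singled out after its values were seen, was at least 156-fold lower against a floor of 3 counts over the 6 libraries together. The list was called by camera (adjusted p = 1.27e-15; adjusted p = 0.444 with an estimated correlation) and by fry (adjusted p = 0.0032). The noncoding imprinted genes MEG3 and H19 read 125 CPM ± 25.9 and 97.1 ± 37.6 in the primary cells (SD, n = 2) and at most 0.0479 and 0.0454 in an H9-derived library. C17orf51 had 0 counts in all 6 and was at least 4090-fold lower, and TYW3, a tRNA modification gene, was lower by -10.39 ± 0.62. Other genes with large decreases spread widely between the primary libraries: CSF3 averaged 864 CPM ± 1110 (-14.26 ± 1.31), CXCL5 3610 ± 4870 (-13.6 ± 1.63), IL1B 262 ± 341 (-13.18 ± 1.35) and the complement gene C3 98.2 ± 107 (-10.11 ± 0.9).

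Camera called 7 further lists, all lower. In the senescence and secretory list 9 of 17 were lower and none higher, the same 9 adjusted over the list alone, among them IL6 (-8.72 ± 1.07), the urokinase receptor PLAUR (-3.63 ± 0.13) and the protease inhibitor TIMP1 (-3.03 ± 0.13) (adjusted p = 0.00123; adjusted p = 0.227 with an estimated correlation). The fibroblast list had 7 of 17 lower on either adjustment, including fibronectin, FN1 (-3.53 ± 0.52), and TWIST2 (-6.18 ± 0.28) (adjusted p = 0.00187; adjusted p = 0.649 with an estimated correlation). Of 14 muscle genes 8 were lower, 9 adjusted over the list alone, with DES (-6.52 ± 0.43) and MYL9 (-3.71 ± 0.39) as examples (adjusted p = 0.000223; adjusted p = 0.493 with an estimated correlation). Of 11 endothelial genes 8 were lower on either adjustment, such as PECAM1 (-4.56 ± 0.58) and TEK (-5.29 ± 0.27) (adjusted p = 0.0019; adjusted p = 0.493 with an estimated correlation). The primary libraries were unlike in this list, with mean log2 CPM of 4.02 and 1.8, against -0.51 to 0.98 in the H9-derived libraries. Interferon-linked and antigen presentation genes had 12 of 20 lower, 13 adjusted over the list alone, with HLA-B (-4.67 ± 0.67) and PSMB9 (-5.05 ± 0.84) among them (adjusted p = 0.000367; adjusted p = 0.399 with an estimated correlation). Cell cycle genes were lower by less: 18 of 30, or 23 adjusted over the list alone, with a median of -0.8 and CCNB1, a mitotic cyclin, at -1.25 ± 0.12 (adjusted p = 6.15e-07; adjusted p = 0.537 with an estimated correlation). The repair Schwann list had 8 of 15 lower on either adjustment, such as the cytokine gene CLCF1 (-3.44 ± 0.48), and 1 higher, the neuropeptide precursor VGF (4.4 ± 0.72) (adjusted p = 0.0354; adjusted p = 0.548 with an estimated correlation). The fibroblast list was not lower in each H9-derived library: its mean log2 CPM was 8.16 to 8.36 at day 25 and in day 50 replicate 1, against 8.23 and 9.12 in the primary cells, and 2.05 to 3.27 in the other 3. The repair list likewise read 4.11 to 4.26 in those libraries, between the primary values of 5.4 and 3.89, then 3.55 in day 50 replicate 2 and 1.34 and 0.53 at day 100. Of these lists fry did not call the fibroblast (adjusted p = 0.0594) and repair lists (adjusted p = 0.125).

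Camera called none of the remaining lists, while fry called the pluripotency (adjusted p = 0.00161), neuronal (0.0337), immune (0.0139) and neurotrophic factor lists (0.0339). Among 11 pluripotency genes POU5F1 stayed near 2 CPM on both sides (log2 fold 0.08 ± 0.45, adjusted p = 0.92), while 4 were higher and 1 lower on either adjustment. The let-7 inhibitor LIN28B averaged 24.4 CPM ± 15.8 in the H9-derived libraries (SD, n = 6) and 0.013 ± 0.0184 in the primary ones (SD, n = 2). Neural crest genes had 4 higher and 1 lower of 15, or 4 and 2 adjusted over the list alone. Neuronal genes had 4 higher, among them the islet and motor neuron factor ISL1 (3.8 ± 0.45), and 1 lower of 17. The neuronal list was not above both primary libraries at day 100. Its mean log2 CPM was 1.79 to 2.78 at day 25 and day 50 and 0.19 and -0.5 at day 100, against 0.14 and 0.93 in the primary cells. Epithelial genes had 3 higher, with E-cadherin, CDH1, at 8.9 ± 1.29, and 2 lower of 9, or 3 and 3 adjusted over the list alone; their median was -1.54 while their mean was 0.41 and the test pointed up. Neurotrophic factors had 3 higher and 9 lower of 17, or 3 and 10, with FGF2 at -4.91 ± 0.53 and VEGFA at -2.42 ± 0.32. Basal lamina genes had 2 higher and 6 lower of 19 and immune genes 4 lower of 8, on either adjustment. Glycolysis genes had 1 higher and 3 lower of 20, and glucose response genes 2 higher and 2 lower of 11 on either adjustment, including GFPT2 of the hexosamine pathway (-4.69 ± 0.2); in the latter the median of 0.36 and the mean of -0.04 had opposite signs. Single members passed in the cholesterol and fatty acid list (1 higher, 1 lower of 23), oxidative phosphorylation (1 higher of 27), ER stress (2 higher of 15) and immediate-early and heat-shock genes (2 lower of 14), and none of 40 ribosomal protein genes did. Over the list alone the cholesterol and oxidative phosphorylation counts fell to 0 and the others were as given. The myelin, cholesterol and immediate-early lists also had a median, a mean and a test that did not share a sign, at medians of -0.46, -0.07 and -0.09.

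Over all genes, 4264 of 17295 differed, 1747 higher and 2517 lower by the edgeR quasi-likelihood test. Other genes ranked among the largest increases: TYRP1 (10.87 ± 1.32) and OCA2 (10.29 ± 0.78) of pigment synthesis, the brain proteoglycan BCAN (10.33 ± 1.11), and P-cadherin, CDH3 (9.87 ± 0.62). ACP5, a lysosomal phosphatase gene, rose by 9.18 ± 0.37. The count was 2080 or 2024 without day 25 replicate 1 or 2, 2442 or 1749 without primary replicate 1 or 2, 6110 without day 50 replicate 1, and 5979 without both day 50 libraries, a setting chosen after seeing the data. Against the shared primary libraries, 3103 genes differed at day 25, 1997 at day 50 and 3428 at day 100, or 5807, 2787 and 5609 without day 50 replicate 1. Leaving out single libraries moved these over ranges of 175 (without day 25 replicate 2) to 5820 (without day 50 replicate 2), 572 (without primary replicate 2) to 3735 (without day 50 replicate 2) and 710 (without day 100 replicate 2) to 5618 (without day 50 replicate 2). Where a group kept a lone library, it was assumed to vary like the other groups.

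**Figure D2:**
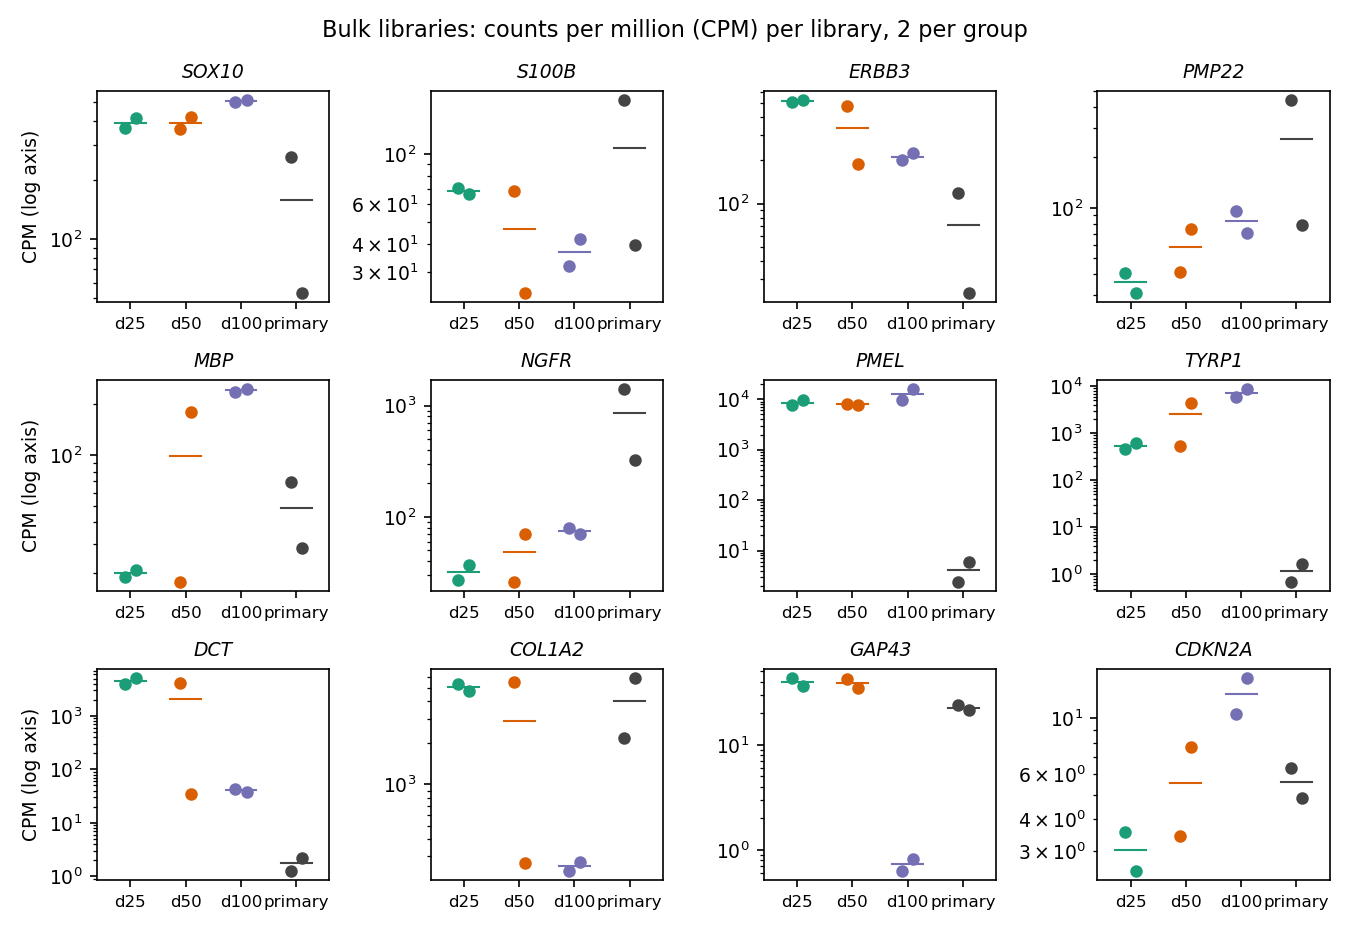
Levels of 12 genes in each bulk library in CPM on a log axis, by group (d25, d50 and d100 are H9-derived), with points for libraries and bars for group means of 2. PMEL lies between 7590 and 15900 CPM in the H9-derived libraries and averages 4.19 in the primary ones, and GAP43 averages 0.727 at day 100.

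Day 100 was compared with day 25 to ask how the derived cells change with longer culture. Genes of several functions fell. GAP43, a growth-cone protein gene of immature Schwann cells, fell from 39.7 CPM ± 4.98 to 0.727 ± 0.129 (SD, n = 2 each), a log2 fold of -5.77 ± 0.27 (SE, adjusted p = 0.0042). VCAN fell from 1070 CPM ± 65 to 3.52 ± 0.706 (-8.25 ± 1.38, adjusted p = 0.046), and CCND2, a D-type cyclin gene, from 127 ± 2.03 to 0.158 ± 0.127 (-9.65 ± 1.5, adjusted p = 0.04). The gelatinase gene MMP9 (-9.42 ± 1.58), the collagen genes COL22A1 (-9.39 ± 0.87) and COL14A1 (-8.95 ± 1.5), the desmosomal gene DSP (-8.53 ± 1.17), C8orf4 (-8.38 ± 1.22) and the synaptic adhesion gene LRRC4B (-8.13 ± 1.01) also fell. Both genes that rose in the fit of all 8 libraries, LOC654433 and XLOC_006252, are unnamed loci that were chosen after their values were seen.

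Schwann markers did not pass the test between day 25 and day 100. MBP averaged 20.1 CPM ± 1.3 and 241 ± 6.2 (log2 fold 3.59 ± 1.02, adjusted p = 0.094) and SOX10 391 ± 33 and 504 ± 7.1 (0.37 ± 0.62, adjusted p = 0.71). S100B (-0.9 ± 0.72), ERBB3 (-1.28 ± 0.73), PMP22 (1.21 ± 0.73), NGFR (1.22 ± 0.72), GFAP (-0.07 ± 1.33) and POU5F1 (0.9 ± 0.55) did not pass either. In a fit of these groups alone, MBP (3.60 ± 0.12), S100B (-0.90 ± 0.16) and ERBB3 (-1.27 ± 0.11) passed; the biological coefficient of variation was 0.177 in that fit and 0.377 over all 8 libraries. None of 19 Schwann lineage genes or 19 myelin genes passed with all 8 libraries, also over the lists alone. In the fit of these groups alone 12 lineage genes were lower and 3 higher, and 7 myelin genes lower and 2 higher; without day 50 replicate 1 it was 4 lower, and 5 lower and 1 higher. Of 16 immature and precursor genes, 3 fell on either adjustment: GAP43, the intermediate filament gene NES (-2.31 ± 0.19) and N-cadherin, CDH2 (-2.11 ± 0.31); 8 were lower and 3 higher in the fit of these groups alone.

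Fibroblast genes were lower as a group, with a median log2 fold of -5.77: TWIST2, from 0.43 to 0.0351 CPM, was lower, 1 of 17, and 16 fell when adjusted over the list alone (adjusted p = 9.48e-07; adjusted p = 0.569 with an estimated correlation). The fibronectin gene FN1 did not pass over all genes (-3.48 ± 0.77, adjusted p = 0.083). Neuronal genes had 1 lower of 17, the synaptic vesicle gene SYT1 (-3.72 ± 0.4), and 11 lower over the list alone (adjusted p = 5.98e-05; adjusted p = 0.569 with an estimated correlation; fry adjusted p = 0.0211). The repair list had 2 lower of 15, TNC (-8.11 ± 1.37) and MMP9, and 7 over the list alone (adjusted p = 0.00867; adjusted p = 0.569 with an estimated correlation). Muscle genes had 1 lower of 14, TAGLN (-4.82 ± 0.6), or 5 lower and 1 higher over the list alone (adjusted p = 0.00104; adjusted p = 0.569 with an estimated correlation). None of 17 neurotrophic factor genes passed over all genes, and 10 were lower and 2 higher over the list alone (adjusted p = 0.022; adjusted p = 0.569 with an estimated correlation; fry adjusted p = 0.0374). BDNF averaged 42.2 CPM ± 6.99 and then 0.333 ± 0.0208. In the fit of day 25 and day 100 alone, 17 fibroblast genes were lower, 11 neuronal genes lower and 1 higher, 8 repair genes lower and 1 higher, 9 muscle genes lower and 1 higher, and 11 neurotrophic genes lower and 3 higher.

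Cell cycle genes pointed up with a median of 0.97: none of 30 passed over all genes, and 27 were higher over the list alone (adjusted p = 5.49e-09; adjusted p = 0.569 with an estimated correlation). Cholesterol and fatty acid genes had a median of 0.71, with none of 23 past the test and 5 higher over the list alone (adjusted p = 0.000654; adjusted p = 0.569 with an estimated correlation). None of 11 melanocyte genes passed over all genes; over the list alone 5 were higher and 1 was lower (adjusted p = 0.0333; adjusted p = 0.569 with an estimated correlation). Within that list MLANA averaged 256 CPM ± 28 and then 1140 ± 16.9, while DCT averaged 4550 ± 792 and then 40.7 ± 4.21. Glycolysis and oxidative phosphorylation pointed up, each at adjusted p = 0.0333, with no member past either adjustment (adjusted p = 0.619 and adjusted p = 0.77 with an estimated correlation). These zeros belong to the fit of all 8 libraries. In the fit of day 25 and day 100 alone, 27 cell cycle genes were higher, 16 cholesterol genes higher and 1 lower, 6 melanocyte genes higher and 1 lower, 9 glycolysis genes higher and 2 lower, and 4 oxidative phosphorylation genes higher. Without day 50 replicate 1 the higher ones were 25, 12, 5, 6 and 1 in that order, with 1 lower in each of the cholesterol, melanocyte and glycolysis lists.

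The other lists were not called by camera or fry. Single members fell in the neural crest list (ZIC1, -6.91 ± 0.94, 6 lower over the list alone), the glucose response list (GFPT2, -1.86 ± 0.28), the immune list (CD74, -5.27 ± 0.91, with 1 higher and 1 lower over the list alone) and the immediate-early and heat-shock list (HSPA1A, -4.17 ± 0.71). No member passed over all genes in the others, whose counts over the list alone were 1 lower for pluripotency, 1 lower for endothelial, 1 higher and 3 lower for epithelial, 2 higher and 2 lower for senescence, 1 higher and 4 lower for basal lamina, and 5 higher and 3 lower for interferon genes. ER stress, HOX and ribosomal protein genes had none on either adjustment with all 8 libraries. In the fit of day 25 and day 100 alone, lower and higher members were 8 and 4 for neural crest, 3 and 2 for glucose response, 1 and 1 for immune, 1 and 4 for immediate-early and heat-shock, 5 and 1 for pluripotency, 4 and 1 for endothelial, 5 and 1 for epithelial, 4 and 3 for senescence, 10 and 3 for basal lamina, 4 and 8 for interferon, 2 and 1 for ER stress, 0 and 5 for HOX, and 0 and 1 for ribosomal protein genes. Without day 50 replicate 1, 7 HOX genes were higher, and camera called the HOX (adjusted p = 0.00242), basal lamina (0.0217) and Schwann lineage lists (0.0499) but not oxidative phosphorylation (0.0638). An estimated correlation was not run in that setting; with all 8 libraries it gave adjusted p = 0.77, 0.619 and 0.77 for the lists called. Of 31 HOX genes, 20 had 0 counts in at least 1 of these groups, and most of those were at or under the floor of 0.036 CPM in both. The HOX median was 0.8, or 1.97 with genes at the floor in both groups left out and the rest of the 20 at their bound.

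In all, 303 genes differed between day 100 and day 25, 2 higher and 301 lower, in the fit of all 8 libraries. In the fit of these groups alone 6875 did, 3048 higher and 3827 lower, which held 302 of the 303. The count was 3 without either day 25 library, 104 or 82 without primary replicate 1 or 2, and 4923 (2000 higher) or 4906 (1962 higher) without day 50 replicate 1 or 2. Without day 100 replicate 1 or 2 it was 0 by edgeR, with 3651 or 2920 genes at an unadjusted p under 0.05, while DESeq2 on all 8 libraries called 3745, 1371 higher and 2374 lower. The near absence of increases therefore held in only some settings.

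The steps in between were read with the odd place of day 50 replicate 1 in mind. From day 50 to day 100, 189 genes fell and none rose by edgeR, with 2264 at an unadjusted p under 0.05, and DESeq2 called 3 higher and 1345 lower. CD24, a surface glycoprotein gene, fell from 70.2 CPM ± 20.5 to 0.899 ± 0.078 (SD, n = 2 each; -6.28 ± 0.34, adjusted p = 0.0048), the collapsin response gene DPYSL5 by 6.18 ± 0.36, GAP43 by 5.73 ± 0.27 and the glutamine transporter gene SLC38A1 by 5.63 ± 0.33. The phosphatase PTPRD (-6.77 ± 1.01), urokinase, PLAU (-6.32 ± 0.61), ADAM19 (-6.29 ± 0.76) and the glypican GPC4 (-5.77 ± 0.65) fell too. Camera called 14 lists, none with an estimated correlation (each at adjusted p = 0.321 or above), and fry called the neuronal list (adjusted p = 0.0326). Neuronal genes had a median of -3.71 and 1 lower of 17, or 11 over the list alone (adjusted p = 0.321 with an estimated correlation). The count of lists was 7 without day 100 replicate 2. The count of genes was 324 without day 50 replicate 1, 3467 (1131 higher and 2336 lower) without day 50 replicate 2, 4 without either day 25 library and 53 without either primary library. It was 0 by edgeR without day 100 replicate 1 or 2, with 2077 or 1006 at an unadjusted p under 0.05.

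From day 25 to day 50 edgeR called 0 genes, with 263 at an unadjusted p under 0.05, and DESeq2 called 4. Without day 50 replicate 1, 1945 genes differed, 887 higher and 1058 lower, including 13 of 17 fibroblast genes lower and 18 of 31 HOX genes higher. Camera called 9 lists, none with an estimated correlation (adjusted p = 0.825 for each) and none by fry. Fibroblast genes pointed down (median -0.83, adjusted p = 3.52e-07) and HOX genes up (median 5.54, or 5.17 at the bound; adjusted p = 3.11e-08), each at adjusted p = 0.825 with an estimated correlation. The value at the bound leaves out HOX genes at or under the floor in both groups. Without day 50 replicate 2 camera called 0 lists. HOXB9, a trunk segment gene chosen after its values were seen, read 24.2 CPM in day 50 replicate 2, at most 0.0248 in the other H9-derived libraries, and 5.18 and 4.55 in the primary ones.

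Expression across genes was correlated with the primary libraries to ask whether resemblance grew with time. Spearman's rho across 17295 genes averaged 0.885 and 0.883 for the day 25 libraries, 0.885 and 0.889 for day 50 and 0.862 and 0.869 for day 100; genes are not independent replicates, and no test was run on these 6 values.

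The single-cell libraries were compared to ask how the derived cells change with passage. With 1 library at each passage, ratios are given with 95% exact intervals for counting error and no test. CDKN2A, which encodes the cell cycle inhibitor p16, had the highest ratio among the genes counted: it read 1.78 CPM at low and 93.4 at high passage, a ratio of 52.4 (45.5 to 60.8). MLANA, a melanosome protein gene, went from 71.2 to 682 CPM, a ratio of 9.57 (9.35 to 9.80), and TXNIP, a glucose-responsive inhibitor of thioredoxin, from 4.39 to 122 (ratio 27.9). HMGCS1, an early enzyme of cholesterol synthesis, stood at 997 CPM at low and 80.3 at high passage, a ratio of 0.0805 (0.0790 to 0.0820), and CXCL8, a neutrophil chemokine gene, was 43.5-fold lower.

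Of 3073 genes at 50 CPM or more in either library, 96 were at least 2-fold higher and 156 at least 2-fold lower at high passage; 19431 genes were listed in both files, and the 979 and 1025 listed in only the low or the high passage file were left out of ratios. Further high ratios were those of S100A1 (30.5), a calcium-binding protein gene, RGS2 (21.8), a G-protein signalling regulator, the neuronal vesicle gene NSG1 (19.6), the protocadherin PCDH7 (12.9), the serotonin receptor HTR2B (12.1), the transcription factor SOX4 (9.68) and SERPINF1 (7.81). Low ratios were those of the secreted hormone STC1 (0.0348), the metallothionein MT2A (0.0488), DCBLD2 (0.0873), VGF (0.0946), the sterol sensor INSIG1 (0.0986), TNFRSF12A (0.1), FGFBP3 (0.113) and the AP-1 gene FOSL1 (0.114). Among fixed Schwann markers ERBB3 had a ratio of 2.51 (2.44 to 2.58) and NGFR was 2.00-fold lower, from 90.2 to 45.1 CPM. SOX10 (1.24), S100B (1.59), MBP (1.43) and PMP22 (1.2) were within 2-fold. GFAP had 12 counts at low passage and is not listed at high passage, and POU5F1 had 9 and 7 counts, a ratio of 0.54 (0.171 to 1.63).

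**Figure D3:**
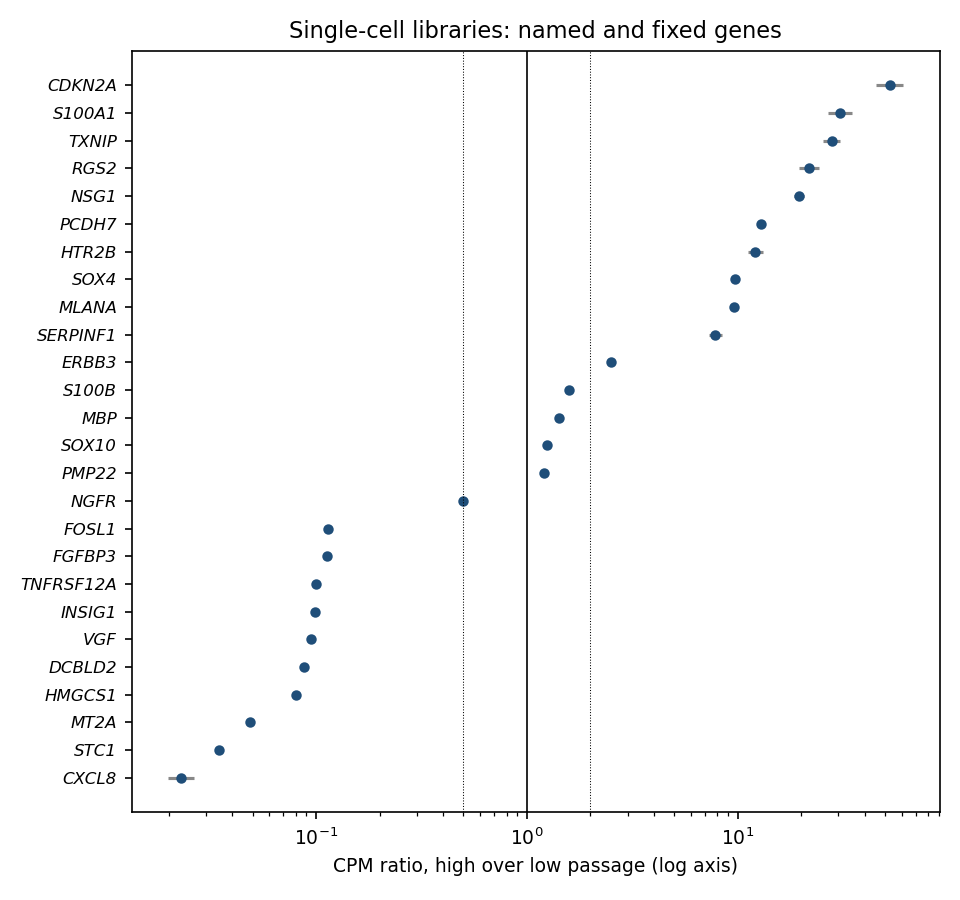
Ratio of CPM at high over low passage for named and fixed genes on a log axis, with 95% intervals for counting error and dotted lines at 2-fold. CDKN2A has the highest ratio (52.4) and CXCL8 the lowest (0.0230).

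List medians of log2 ratios were set against 10000 random lists matched on expression. Cholesterol and fatty acid genes were lower together: all 24 measured had a ratio below 1, 21 of them at least 2-fold, with a median of -1.68 (middle 95% of random lists -0.23 to 0.13). SCD, a fatty acid desaturase gene, went from 777 to 168 CPM and FDPS from 697 to 177. In the repair Schwann list 6 of 7 were at least 2-fold lower (median -3.4), with VGF at 10.6-fold and the chemokine CCL2 at 15.7-fold, while JUN, a driver of the repair state, had a ratio of 3.85. In the senescence and secretory list 7 of 13 were at least 2-fold lower (median -2.52), including STC1 and the p53 target CDKN1A (7.12-fold), while CDKN2A was higher. Stress and metabolic lists were lower by less: ER stress -0.87, with the chaperone HSP90B1 1.84-fold lower, glycolysis -0.65, with the pyruvate kinase PKM 1.82-fold lower, immediate-early and heat-shock -0.57, and cell cycle -0.3. Shares of cycling clusters had no settled direction: they held 8.61% of low and 24.0% of high passage cells at resolution 0.5, but 3808 low and 2144 high passage cells made up the main ones at resolution 0.25. The neuronal list, with 3 measured members, stood at -1.11, though MAP2 had a ratio of 44.7.

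Melanocyte genes were higher together at a median of 1.7 (random lists -0.36 to 0.29): 7 of 10 were at least 2-fold higher, with MITF at a ratio of 2.11 and TYRP1 at 7.16, and DCT, from 118.5 to 31.7 CPM, was lower. Neural crest genes had a median of 0.88, with 4 of 10 at least 2-fold higher, MEF2C (3.82) among them, and 1 at least 2-fold lower, MSX1 (40.4-fold), chosen after its values were seen. MSX1 read 300 CPM in the mesenchymal-like cluster described below and at most 20.4 in the others, and that cluster was rarer at high passage. The Schwann lineage list had a median of 0.5 over 13 genes, 3 of them at least 2-fold higher, and none 2-fold lower. Endothelial (0.99, 3 members), epithelial (0.59, 5 members) and oxidative phosphorylation genes (0.13, 27 members) also lay above random lists. Medians inside the random range were those of myelin (0.26), immature and precursor Schwann (0.03), fibroblast (0.03), interferon (0.06), basal lamina (0.02), ribosomal protein (-0.01), neurotrophic (-0.28), pluripotency (-0.34), glucose response (-0.35) and muscle genes (-0.39, a sign that turned to 0.33 with the stricter cell filter, 0.12 in thinned cells and 0.14 per cell). HOX and immune genes had too few members above 5 CPM for a median.

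**Figure D4:**
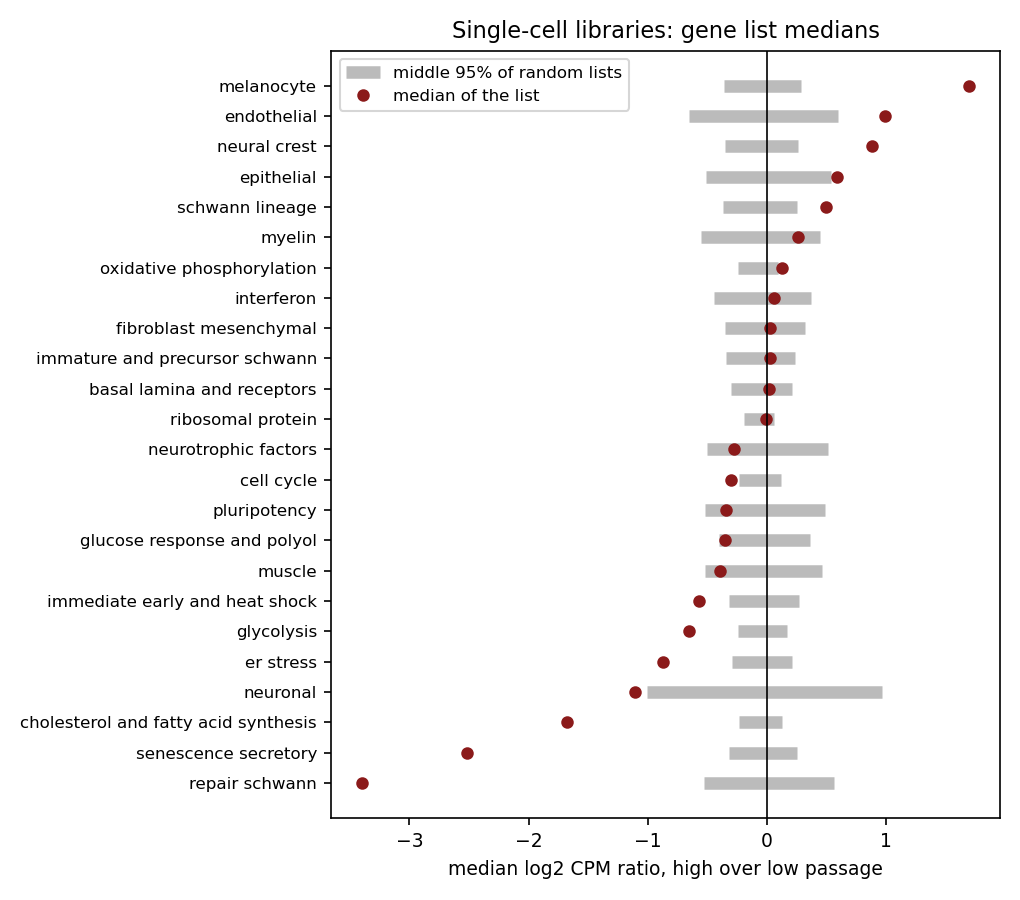
Median log2 ratio of CPM, high over low passage, for each gene list (points) and the middle 95% of 10000 expression-matched random lists (grey bars). The melanocyte list lies above its bar at 1.7 and the cholesterol and fatty acid list below its bar at -1.68.

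After removal of damaged and doublet barcodes, 15340 cells at low and 19981 at high passage remained, with medians of 7382 and 7337 molecules. These still included clusters of few molecules: 2212 low passage cells (14.4%) lay in a cluster with medians of 1014 molecules and 0.39% mitochondrial counts, 1685 (11%) in a cluster with 1952 and 13.1%, and 643 high passage cells (3.22%) in a cluster with 1082 and 0.311%. Of 13 clusters, 1 met the marker rule for Schwann cells, with 9 markers including SOX10 and ERBB3. It held 2861 high passage cells (14.3%, 13.8 to 14.8) and 1 low passage cell. Clusters other than the mesenchymal-like one described below all came almost wholly from 1 library, so this is not particular to it. A Schwann-like state shared by most cells would go unnamed, since markers had to stand 2-fold above all other cells. SOX10 read 127 CPM in the largest low passage cluster and 126 in the largest high passage one. In the same order NGFR read 98.2 and 18.0, and ERBB3 69.8 and 133. With each library clustered on its own, a setting chosen after seeing the data, a cluster of 2920 high passage cells (14.6%) also met the rule with 9 markers, and none did at low passage. Without the filters on genes and mitochondrial counts, and with doublets still removed, Schwann-like clusters took 17.6% of low passage barcodes against 12.8% at high passage, so the difference of 14.3 percentage points turned to -4.8. The cluster behind this turn, named on 3 markers, held 3681 low passage barcodes with medians of 26.6% mitochondrial counts and 2146 molecules. A mesenchymal-like cluster held 729 low (4.75%, 4.42 to 5.1) and 155 high passage cells (0.776%, 0.659 to 0.907), and a melanocyte-like cluster 95 low passage cells (0.619%) and 0 of 19981 at high passage, which allows up to 0.0185%; in cells thinned to 2000 molecules a cluster named melanocyte-like held 16 low and 12229 high passage cells. The other 94.6% and 84.9% of cells met no marker rule.

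Marker detection was compared after thinning each cell to 2000 molecules, which left out 3080 low and 747 high passage cells. For glial and pigment genes, shares in the mesenchymal-like cluster, which should lack them, stand for background. Its median depths were 7053 and 6140 molecules. PMEL was detected in 50.5% of low and 74.3% of high passage cells (16.4% and 22.8% in the mesenchymal-like cluster; unthinned 75.2% and 91.4% of all cells). SOX10 was detected in 20.5% and 25.2% (background 3.81% and 6.04%; unthinned 47.7% and 59.6%), and ERBB3 in 12.3% and 25.5% (background 2.82% and 3.36%; unthinned 31.5% and 59.5%). MLANA was detected in 7.17% and 61.9% (background 0.846% and 21.5%, unthinned 15.8% and 85.2%). CDKN2A was detected in 0.343% and 15.9% (0.141% and 7.38% in the mesenchymal-like cluster, unthinned 1.08% and 42.5% of all cells). Whether the mesenchymal-like cells themselves express CDKN2A was not tested, so their share is not a background for this gene.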

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

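For the first and second patterns below the tests were chosen after the result was seen; in the third so was the use of the cell cycle list, and its other tests were written down before.

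In primary replicate 2, 6.0% of reads overlapped more than 1 gene and were not counted, against 2.41% to 2.61% in the other bulk libraries, a signal in reads that the comparisons do not use. Barcodes with over 20% mitochondrial counts, which the comparisons also leave out, made up 21.2% of the low passage library (20.6 to 21.7) and 8.75% of the high passage library (8.4 to 9.11).

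The library labelled day 50 replicate 1 lay beside the day 25 libraries, and day 50 replicate 2 beside day 100. The tables argue against 1 library deposited in duplicate, since its counts differed from those of day 25 replicate 1 by 1.76 times the chance spread. They argue against a swap that put a library like day 50 replicate 2 under a day 25 label. The nearest day 25 library lay 29.1 times as far from day 50 replicate 2 as the day 25 libraries lay from each other. A swap of day 50 replicate 1 with a day 25 library cannot be judged from such distances. It lay 1.76 and 2.25 times the chance spread from day 25 replicates 1 and 2, and those lay 2.43 times from each other. Day 25 material under a day 50 label is a candidate explanation: the distance of day 50 replicate 1 to its nearest day 25 library was 0.724 of that within day 25. A day 50 culture that had barely changed, which the design could hold, was not tested and stays open. The label of day 50 replicate 2 was not tested in this way. It lay 6.12 times the chance spread from day 100 replicate 1, against 26.5 between the day 100 libraries. Its mean log2 CPM of HOX genes was -0.62, against -3.05 and -3.08 at day 100.

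Melanocyte genes were abundant in the H9-derived cells. PMEL was not confined to the small cluster named melanocyte-like: at low passage 93.0% of its counts lay outside that cluster. It read 2650 CPM there, 107 in the mesenchymal-like cluster and 280 to 1170 in the others, with 332 in the Schwann-like one. TYR, by contrast, read 151 CPM in the melanocyte-like cluster and at most 23.0 elsewhere. Clusters were named only where markers stood 2-fold above all other cells, which leaves a group of most cells unnamed. A pigment group of most cells and a state shared by most cells therefore cannot be told apart. In thinned cells a melanocyte-like cluster held 12229 high and 16 low passage cells. Free RNA in the droplets may add some molecules, but PMEL in the mesenchymal-like cluster stood at 0.247 of its level in other cells at high passage (0.217 to 0.28) and 0.164 at low passage (0.149 to 0.18), where free RNA alone needs a ratio of 1. A mixed glial and pigment state also stays open as a hypothesis.

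Cholesterol and fatty acid synthesis genes were lower at high passage, with a median log2 ratio of -1.68. Depth and damaged barcodes are argued against by a median of -1.74 in thinned cells and -1.62 with the stricter barcode filter. A different share of cycling cells as the whole cause is argued against by the cell cycle genes, which such a cause needs to fall as far: their median was -0.3 (-0.39 to -0.11), while the median of -1.83 outside the cycling clusters decides nothing, since which clusters counted as cycling changed with the setting. A different mix of cell types stays open: within the mesenchymal-like cluster, present in both libraries, the median was -0.55 (-0.7 to -0.41), well short of the whole, so the mix may account for part, though at resolution 1.0 this cluster split by library (728 low and 10 high passage cells, and 3 and 146), so it is not shown to hold 1 kind of cell. An effect of passage itself, as against any other difference between these single libraries, was not tested.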

How the results depend on the processing

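Settings were fixed before the values were known, apart from the H9-derived mean without the day 50 libraries and the clustering of each library on its own, which were chosen after seeing the data. With each library left out in turn, genes changed ranged from 0 to 1945 (day 50 vs day 25), 0 to 3467 (day 100 vs day 50), 0 to 4923 (day 100 vs day 25), 1749 to 6279 (H9-derived mean vs primary), and 175 to 5820, 572 to 3735 and 710 to 5618 (day 25, 50 and 100 vs primary); a lone library was assumed to vary like the other groups. Of these 56 counts, 12 stayed within 1.5 times the reported one and 44 did not; in each day contrast the highest count came with a day 50 library left out, and counts of 0 by edgeR went with 17 to 3651 genes at an unadjusted p under 0.05. DESeq2 was run on all 8 libraries. Lists called ranged from 0 to 10, 7 to 16, 7 to 12 and 9 to 15 in the first 4 contrasts.

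Under the other settings 37 of 63 counts stayed within 1.5 times. DESeq2 gave 4, 1348 and 3745 genes for the day contrasts in that order, and 4876 and 3743 for day 25 and day 50 vs primary. Without a low-count filter the last pair of day contrasts gave 403 and 873, and with 10 CPM in 2 libraries 81 and 123, with 2656 for the H9-derived mean and 1240 and 1930 for day 50 and day 100 vs primary. Against a fold of 2, a stricter null by construction, glmTreat gave 113, 160, 1603, 853, 642 and 1548 for day 100 vs day 50, day 100 vs day 25, the H9-derived mean, and day 25, 50 and 100 vs primary. Fits of only the groups compared gave 0 genes for day 100 vs day 50 by edgeR, with 1251 at an unadjusted p under 0.05, and 6875 for day 100 vs day 25, 5902 for day 25 vs primary and 64 for day 50 vs primary. The replicate block gave 4, 149, 1986 and 1056 for day 100 vs day 50, day 100 vs day 25, day 25 vs primary and day 50 vs primary; replicate differences correlated across genes at -0.27 to 0.17 between groups, so replicate numbers do not pair the samples. With an estimated correlation camera called 0 lists in each of 4 contrasts, and fry called 0, 1 and 2 in the day contrasts and 11 for the H9-derived mean, where camera called 9. Correlations with primary for days 25, 50 and 100 were 0.762, 0.775 and 0.755 over genes at 10 CPM and 0.861, 0.864 and 0.838 by Pearson. Apart from the size of a fold and the number of samples fitted, the cause was not tested.

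In single cells 731 genes were 2-fold different at a CPM minimum of 10, and the other 6 settings stayed within 1.5 times of 252. The Schwann-like share, high minus low passage, was 14.8 and 13.1 percentage points at resolutions 1.0 and 0.25, 15.9 with the stricter barcode filter, 9.65 in thinned cells and -4.8 without the filters on genes and mitochondrial counts. That reversal came with a cluster of 3681 low passage barcodes at a median of 26.6% mitochondrial counts; the cause was not tested. The difference was 14.6 with each library clustered on its own. For the gene lists, all 150 values under alternatives stayed near the reported ones. Each list median moved by less than its spread, and the count of lists outside the random range stayed within 1.5 times of 14. Medians inside the random range changed sign under some settings, namely muscle as given above, immature and precursor Schwann (-0.08 to -0.04), basal lamina (-0.09 to -0.04), fibroblast (-0.03 and -0.02) and ribosomal protein genes (0.01 to 0.03). Depth limits rare genes: 3073 of 19431 reached 50 CPM. Planted ratios of 2 and 0.5, which lie at the threshold itself, were called in 32 and 28 of 50 genes.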

Other observations

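The tests of explanations in this part were written down before the result was seen; the genes in the opening paragraphs were chosen after their values were seen.

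Some H9-derived libraries differed in immediate-early genes, which cells switch on within minutes of handling or growth factor stimulation. FOS, an AP-1 gene, read 490 CPM in day 50 replicate 2 and 663 in day 100 replicate 1, but 12.8 in day 100 replicate 2 and 28.7 and 28.9 at day 25. EGR1 read 331, 455, 2.8, 26.7 and 26.4 CPM, and JUN, which drives the repair state of Schwann cells after nerve injury, 418, 538, 36, 63.3 and 64.2, in the same order. The spread therefore lay within day 100 as much as between days.

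Single genes with wide differences did not pass the test with all libraries. IGFBP5 averaged 10200 CPM ± 439 at day 25 and 10.4 ± 5.9 at day 100 (SD, n = 2 each; log2 fold -9.93 ± 2.51, adjusted p = 0.092), and LGI4, a secreted Schwann cell factor needed for myelination, 48.2 ± 6.99 and 0.223 ± 0.0699 (-7.73 ± 1.94, adjusted p = 0.092). CDKN2A averaged 3.04 ± 0.743 and 12.4 ± 2.78 (2.02 ± 0.47, adjusted p = 0.089), the direction it took with passage in single cells. Cholesterol genes did not share a direction between the data sets, with a median of 0.71 from day 25 to day 100 in bulk and -1.68 from low to high passage.

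A hypothesis was tested that later days and higher passage share a direction. Of the genes lower at day 100 than at day 25, 273 were listed in the single-cell files and 61 could be measured. Their median log2 ratio of high over low passage was -0.94, below the middle 95% of 10000 random lists (-0.13 to 0.23); 30 were at least 2-fold lower and 4 at least 2-fold higher. SLC38A1 was 24.9-fold lower, the tubulin gene TUBB2B 17.3-fold and GAP43 13.9-fold, while VCAN had a ratio of 2.80 and DSP 3.12. The values go with a shared direction in culture for these genes. With 1 library per passage, a difference between these libraries alone could give them too. Gene lists did not all share a direction. Medians in bulk and then with passage were, for example, -1.42 and -3.4 for repair and 0.59 and 1.7 for melanocyte genes. Signs were opposite for Schwann lineage (-1.06 and 0.5), neural crest (-1.26 and 0.88), cell cycle (0.97 and -0.3) and glycolysis genes (0.32 and -0.65). The mesenchymal-like cluster was also rarer at high passage (0.776% against 4.75% of cells), and fibroblast genes were lower as a group at day 100. With passage, however, the fibroblast list median was 0.03, inside the random range. A different mix of cells was not tested for the 61 genes.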
